A study of Mus musculus with 12 samples.

How the data were processed

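Total RNA of the mouse pro-erythroblast line I/11 was amplified, biotin labelled and hybridised to Affymetrix Mouse Genome arrays, per the labels' protocols. The 12 arrays cover 3 stable shRNA lines (scrambled control scr, and the hairpins sh14 and sh133 against Plcg1) at 4 time points. Each shRNA and time point has 1 array. The values used are the log2 probe set signals deposited in the series table, made with RMA per the submitters' processing notes, with the version not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of each set. The deposited values ran from 0.04 to 13.1 over 45101 probe sets. At matching quantiles the arrays differed by at most 0.295 log2, so differences in total RNA content between arrays cannot be read from these values.

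Probe sets were named from the platform annotation. It gave 1 gene for 34958 probe sets, several for 932 and none for 9211, and 34754 of those with 1 gene were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6. That table served only for current symbols, chromosomes and the order of genes. The probe set of highest mean over the 12 arrays stood for each of 18194 genes, and genes below the 40th percentile of probe set means (log2 1.45) were left out, which left 12673 genes. Probe sets of several genes were not used. No column of per-sample values was left unused.

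Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values, with moderated variances and Benjamini-Hochberg adjustment over the 12673 genes. Unless another fit or adjustment is named beside it, an adjusted p of a gene comes from this model, and the threshold was 0.05. The model held shRNA, time as a factor, and array run. The array titles carry 2 different date strings, on 6 arrays each, which were read as 2 array runs. The labels do not say what the dates record. This model left 5 residual degrees of freedom. Comparisons were both hairpins against scr (8 arrays against 4), each hairpin against scr, sh14 against sh133, 22 h, 6 h and 12 h against 1 h, and knockdown by time. The last is the difference between the hairpins' and scr's slopes on log2 hours, in log2 units per doubling of hours, with 4 residual degrees of freedom. Arrays of the same time were matched across shRNAs by the time term. Replicate numbers within an shRNA follow deposit order and pair nothing.

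Of 34 gene lists fixed beforehand, 33 had at least 5 tested genes. The list of embryonic and fetal globins had 2 and was not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists within a comparison, and again with an estimated correlation. Members were also counted after adjustment over the list alone. The agreement of the hairpins was set against 100 simulated draws of unchanged hairpin groups against the same scr arrays. Neighbouring genes were compared in map order by the median of 41 consecutive tested genes, with 1000 shuffles of gene order, and chromosome shares of called genes with a one-sided Fisher's exact test. Figures were drawn with Python 3.11.15.

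Named genes follow a rule: Plcg1, Plcg2, Epor, Jak2, Stat5a, Stat5b, Gata1, Klf1, Kit and Myb always, then up to 12 genes in each direction for the knockdown, 22 h and knockdown by time comparisons. These had the largest change among called genes of the same sign in every matched difference. For sh14 against sh133 the rule took 5 in each direction, and from each list described up to 4 members of largest change. Where fewer than 5 genes passed in a direction, the 5 of smallest p were taken and are given as not past the threshold. Predicted genes were counted but not named. Genes outside this rule that are named were chosen after their values were seen, and are marked so where they appear. The lists, the rule, the model and the alternatives were set before the data were examined, except those said to be added later.

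The pipeline was tested on simulated data, with 200 changed genes in each of 5 draws over 12673 genes. For knockdown against scr it recovered 29.6% of 1.5-fold, 70.4% of 2-fold and 97.0% of 4-fold changes, and 4.8% of its calls were false. For 22 h against 1 h the recovery was 61.8%, 89.9% and 99.7%, with 3.7% false calls. For knockdown by time, changes of these sizes reached by 22 h were recovered at 0.3%, 19.7% and 82.4%, with 4.2% false calls. The simulated noise was normal and independent between genes and arrays. Differences between the lines beyond the planted changes, time courses particular to a line and neighbouring genes moving together were absent. The false calls that these would add are not measured. The number of arrays limits the precision. The median standard error of a gene's log2 difference was 0.15 for knockdown, 0.11 for 22 h against 1 h, and 0.17 for the array run term.

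The alternatives were no array run term, no filter or a filter at the 60th percentile, the mean over a gene's probe sets or each probe set by itself, and quantile normalization or each array centred on its own median. A trend and robust prior, array weights, a line in log2 hours, no time term, fits within run 1 or run 2, fits on subsets of arrays and leaving out each array were tried too. Leaving out the genes of chromosome 12, or of chromosomes 10 and 12, was added after the data were seen. Signals of named genes at or below the highest array median (1.92) are described as near background, a rule added after the data were seen. Some results are left out of the text, and the counts of genes and lists include them.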

Results

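I/11 cells are immature erythroid progenitors that were established from fetal liver of mice lacking p53 and can be expanded in culture with erythropoietin, stem cell factor and dexamethasone. Lines stably carrying a scrambled shRNA (scr) or either of 2 hairpins against Plcg1 (sh14 and sh133) were sampled at 1, 6, 12 and 22 h, and each sample was measured on 1 array. The labels do not say from which event the hours were counted. Each shRNA thus has 4 arrays that differ in time, and a standard deviation over them includes the change with time. The array titles carry 2 date strings, read here as 2 array runs, though the labels do not say what the dates record. Run 1 held all sh14 arrays and sh133 at 6 and 12 h, and run 2 held all scr arrays and sh133 at 1 and 22 h. No scr array shared a run with an sh14 array. For the run term itself limma called 0 of 12673 genes, with 694 at an unadjusted p under 0.05, where chance alone gives about 5%. Only sh133 lies in both runs, so the term rests on its 6 and 12 h arrays against its 1 and 22 h arrays. It cannot be told apart from a time course particular to sh133, and 0 calls do not show that the runs were alike. The sh14 and combined knockdown differences depend on this term. Array medians lay between 1.84 and 1.92 log2, and correlations between arrays between 0.971 and 0.997. The difference between 3' and 5' actin probe sets was 0.34 to 0.63 log2, lowest in sh133 at 22 h and highest in scr at 22 h. Nothing in the labels states separate cultures per array. With no repeat array of an shRNA and time, p-values rest on what the additive shRNA, time and run terms leave. That remainder may mix technical spread with time courses that differ between the lines, and it does not measure a spread between cultures. The first principal component (31.7% of the variance) set the 4 sh14 arrays apart from the rest. The second (22.7%) followed time within each shRNA, and the third (16.5%) separated scr from sh133.

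The series asks what Plcg1, a phospholipase C that acts below growth factor receptors, does in erythroid differentiation controlled by the erythropoietin receptor and JAK2. Plcg1 itself, read from its brightest probe set (at the 46.5th percentile of tested genes), had a log2 signal of 4.53 ± 0.19 in scr, 4.15 ± 0.20 in sh14 and 4.41 ± 0.08 in sh133 (SD, n = 4 arrays each). It was below scr at 4 of 4 times in sh14 and at 3 of 4 in sh133. The combined knockdown difference was -0.24 ± 0.17 (SE), with a 95% confidence interval of -0.61 to 0.14 and a limma adjusted p of 0.592, a signal of 85.0% of scr that did not pass the test. The differences were -0.36 for sh14 (adjusted p = 0.456) and -0.11 for sh133 (adjusted p = 0.767). Without the run term, sh14 differed by -0.38 (adjusted p = 0.0201). Within run 2, sh133 minus scr was -0.21 at 1 h and 0.08 at 22 h. The other 2 Plcg1 probe sets, both dimmer, gave -0.15 and 0.22. The series has no protein measurement.

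**Figure D1:**
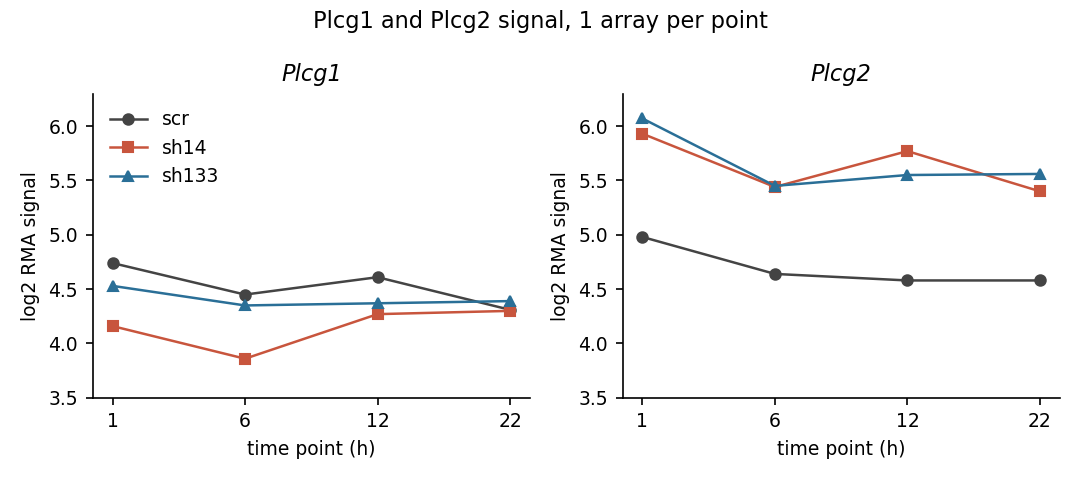
Log2 RMA signal of Plcg1 and Plcg2 (vertical axis) at the 4 time points in hours (evenly spaced on the horizontal axis), 1 array per point, for scr, sh14 and sh133. Plcg2 lies between 4.58 and 4.98 in scr and between 5.40 and 6.07 in the hairpin arrays, while the Plcg1 signals of the lines lie closer together.

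Against scr, both hairpin lines carried more Plcg2, which encodes the sister enzyme PLCγ2, and less Sptbn1, which encodes a beta spectrin of the membrane skeleton. Plcg2 was at 4.70 ± 0.19 in scr, 5.64 ± 0.26 in sh14 and 5.66 ± 0.28 in sh133 (SD, n = 4), 2.15-fold higher with knockdown (log2 1.10 ± 0.13 SE, limma adjusted p = 0.00302). It was higher at all 4 times with each hairpin, by 1.09 and 0.98 at 1 and 22 h within run 2. Sptbn1 was lower (-2.59 ± 0.19, adjusted p = 0.000427), with -3.39 in sh14 and -1.80 in sh133. Its sh14 mean of 1.70 lay below the highest array median (1.92), near background, where the exact size of a difference is uncertain. Mmp2, a matrix metalloproteinase, was 5.34-fold higher (2.42 ± 0.24, adjusted p = 0.00126), at 3.63 in sh133 and 1.21 in sh14, where it missed the threshold (adjusted p = 0.0708).

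Other genes higher with knockdown at every matched time included Ramp1 (1.99), Slc6a13 (1.62), Naip5 (1.53), the histone gene H2aw (1.53), Lpcat2 (1.52), Afp (1.50), Xaf1 (1.49), Ankrd44 (1.49), Plaat3 (1.47) and Galk2 (1.47), with adjusted p from 0.00126 to 0.0371. In scr, Naip5 (1.36), Afp (0.93) and Xaf1 (1.74) were near background, so their sizes are uncertain. The lower genes were led, after Sptbn1, by Tmcc3 (-2.17), Unc13c (-2.06), Fam169a (-1.89), Gucd1 (-1.82), Chchd10 (-1.81), Tbc1d15 (-1.70), Lgr4 (-1.68), Cdca7l (-1.67), Rhobtb1 (-1.60), Bmp2 (-1.53) and Tnfrsf13c (-1.53), with adjusted p from 0.000137 to 0.0196. Without the run term Unc13c was at -1.36 and Bmp2 at -1.01. Cdca7l was at -2.97 in sh14 and -0.37 in sh133 (adjusted p = 0.19). Tmcc3, Gucd1, Chchd10, Tbc1d15 and Rhobtb1 lie on chromosome 10.

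The erythropoietin receptor gene, the signalling genes Jak2, Stat5a and Stat5b, the erythroid regulators Gata1 and Klf1, and Kit and Myb did not pass the test with knockdown. The differences were -0.13 for Epor (adjusted p = 0.777), -0.11 for Jak2 (0.812), 0.17 for Stat5a (0.581), -0.09 for Stat5b (0.877), -0.11 for Gata1 (0.805), -0.27 for Klf1 (0.401), -0.36 for Kit (0.581) and 0.22 for Myb (0.674). In all, limma called 276 of 12673 genes, 144 higher and 132 lower, of which 229 had the same sign in all 8 matched differences. Chromosome 10 held 25.8% of the lower and 16.0% of the higher genes, against 4.8% of the genes tested, and chromosome 12 held 13.6% of the lower genes against 3.6% (one-sided Fisher's exact test, adjusted p = 9.2e-15, 6.1e-06 and 1.3e-05). The count was 150 without the genes of these chromosomes (an alternative added later), 2049 without the run term, and 59 without the sh133 array at 1 h.

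With the run term in the model, the genes of red cell function that passed with knockdown were lower, and those of interferon response were higher. Camera called 12 of 33 lists, and 0 with an estimated correlation. Among 28 terminal erythroid genes, 3 were lower (5 adjusted over the list alone): Epb42, a red cell membrane protein (-0.86 ± 0.16, adjusted p = 0.0242), the Rh antigen gene Rhd (-0.84 ± 0.18, 0.0487) and the mitochondrial iron carrier Slc25a37 (-0.84 ± 0.18, 0.042). Without the run term 5 were lower and 3 higher, and Epb42 differed by -0.36 (adjusted p = 0.0808). The list was called lower by camera (adjusted p = 0.0011, and adjusted p = 0.37 with an estimated correlation), while its medians in sh133 minus scr were -0.10 and -0.01 at 1 and 22 h within run 2, and 0.00 and 0.01 at 6 and 12 h across runs. In sh14 minus scr they were -0.37 to -0.28. Heme synthesis and iron uptake was also called lower (1 of 21 genes, also 1 adjusted over the list alone, adjusted p = 0.0026, and adjusted p = 0.21 with an estimated correlation). Among 12 mast cell and basophil markers, Fcer1a (1.52) and Gata2 (1.03) were higher with knockdown (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.045, adjusted p = 0.37 with an estimated correlation, and 0.073 without the run term). Fcer1a, near background in scr and sh133, was at 3.08 in sh14 and -0.04 in sh133 (adjusted p = 0.956), and the list's medians in sh133 minus scr within run 2 were -0.11 and 0.01.

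Interferon response genes were higher in 3 of 30 cases (7 adjusted over the list alone): Xaf1, the immunoproteasome subunit gene Psmb9 (1.18 ± 0.15, adjusted p = 0.00384) and Oas1a (1.15 ± 0.11, adjusted p = 0.00126). The list's adjusted p was 0.00046, and adjusted p = 0.37 with an estimated correlation; within run 2 its medians were 0.02 and 0.01. S phase and DNA replication had the lowest list p (5.8e-06, and adjusted p = 0.87 with an estimated correlation) with 0 of 49 genes past limma's threshold, and its median within run 2 was 0.20 at 1 h and -0.32 at 22 h. G2-M and mitosis was called lower with 0 of 52 genes passing (adjusted p = 0.011, adjusted p = 0.87 with an estimated correlation, and 0.84 without the run term). Its median was -0.34 in sh14 but 0.08 in sh133, where 37 of 52 members were above scr. Further lists were called, each losing the call with an estimated correlation. Replication-dependent histones were called higher through H2aw (1 of 7 genes, 3 adjusted over the list alone; adjusted p = 0.0014, and adjusted p = 0.21 with an estimated correlation). Progenitor and SCF-Kit genes were called higher with Ets1 (1.09) and Gata2 passing (2 of 23, and 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.58 with an estimated correlation). So were megakaryocyte markers with Cd9 at 0.90 (1 of 19, 2 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). Glycolysis and hypoxia was called lower with Pdk1 at -1.06 (1 of 31, also 1 adjusted over the list alone; adjusted p = 0.04, and adjusted p = 0.80 with an estimated correlation). ATF4 and unfolded protein response was called higher with Herpud1 at 1.07 (1 of 38, and 1 in each direction adjusted over the list alone; adjusted p = 0.044, adjusted p = 0.87 with an estimated correlation, and 0.15 without the run term).

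Among 32 members of the PLC and PKC pathway, 3 were higher and 2 lower (6 and 4 adjusted over the list alone). They included Plcg2, Prkca, which encodes protein kinase C alpha (1.00 ± 0.18, adjusted p = 0.0247), and the adaptor gene Blnk (-1.48 ± 0.18, adjusted p = 0.00301, near background in the hairpin lines), and the list was not called (adjusted p = 0.27). Of 26 EpoR-JAK2 signalling members only the adaptor gene Grb2 passed (0.63 ± 0.13, adjusted p = 0.0406; list adjusted p = 0.56). Of 25 EpoR-STAT5 targets only Tnfrsf13c passed (list adjusted p = 0.45), and of 13 calcium-NFAT targets Plcg2 and Nfatc1 (1.09 ± 0.17, adjusted p = 0.013; list adjusted p = 0.53).

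Against scr, sh14 alone differed in 388 genes (190 higher, 198 lower) and sh133 622 (311 in each direction). They shared 58 higher and 58 lower genes, against 4.7 and 4.9 for independent lists, and 9 genes went opposite ways. Across genes the fold changes of the hairpins correlated at r = 0.43, below the 0.76 that simulated unchanged groups gave against these same scr arrays in the same model. Differences between the hairpin lines, absent from the simulation, also lower r, so the lower value does not show less agreement than chance. The covariance was 0.0499 against a simulated 0.0301 (100 draws). Because scr is common to the differences, an excess is not read as an effect of both hairpins. With the scr arrays split between the hairpins and no run term, r was 0.21 to 0.33 (genes are not independent replicates). In sh14, erythroid terminal genes were lower in 6 of 28 cases (2 higher and 9 lower adjusted over the list alone), among them Alas2 (-1.83), the enzyme of the opening step of heme synthesis, and the anion exchanger gene Slc4a1 (-1.60). Without the run term these were -1.07 (adjusted p = 0.00252) and -0.51 (adjusted p = 0.177). The list's camera adjusted p was 5e-05, and adjusted p = 0.26 with an estimated correlation. In the same arrays 4 of 12 mast cell and basophil markers were higher (5 adjusted over the list alone; camera adjusted p = 0.0021, and adjusted p = 0.26 with an estimated correlation): Fcer1a (3.08), Gata2 (1.53), Ms4a2 (1.36) and Mitf (1.03, named after its value was seen). In sh133, 3 of 7 replication-dependent histone genes were higher (4 adjusted over the list alone), H2aw (1.60), H2bc22 (0.90, near background in scr) and H2ax (0.79), with a camera adjusted p of 6.7e-05, and adjusted p = 0.15 with an estimated correlation. Camera called 10 lists for sh14 and 4 for sh133, and 0 for either with an estimated correlation. Of the genes lower in sh133, 30.3% lay on chromosome 12, against 3.6% of the genes tested. Chromosome 10 held 19.7% of the lower and 15.8% of the higher genes of sh133, against 4.8% of the genes tested. In sh14 it held 17.2% of the lower and 6.3% of the higher genes. Chromosome 6 held 13.2% of the higher genes of sh14, against 5% of the genes tested. Chromosome 13 held 9.1% of the lower and 8.4% of the higher genes of sh14, against 3.5% of the genes tested. The sh133 count was 254 within run 2 alone, and since sh14 and scr shared no run, the sh14 difference has no within-run value.

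The hairpin lines differed from each other in casein genes, Fcer1a, Cxcl3 and Cdh2, and with all arrays more genes passed between them than between either and scr. Without the sh133 array at 6 or 12 h this order turned (413 and 390 genes between them, 424 for sh133 against scr). sh14 exceeded sh133 in the casein genes Csn1s2a (4.19 ± 0.40, adjusted p = 0.000166) and Csn1s2b (3.30), in Sphkap (4.06), in Fcer1a, which encodes the alpha chain of the IgE receptor (3.12 ± 0.23, adjusted p = 3.57e-05), and in Sapcd1 (2.75). sh133 exceeded sh14 in the chemokine gene Cxcl3 (-4.45 ± 0.54, adjusted p = 0.000652), N-cadherin (Cdh2, -3.21 ± 0.16, adjusted p = 5.25e-06), Gstt1 (-3.06), Ly6k (-2.97) and Fkbp9 (-2.95). Cxcl3 was at 0.82 in sh14 and 0.85 in sh133 at 1 h, and its difference without the run term was -2.97. Csn1s2a and Csn1s2b were at 2.92 and 2.25 without that term. Sphkap, Csn1s2b and Fcer1a in sh133 and Cxcl3 in sh14 were near background (means of 1.84, 1.44, 1.08 and 0.84), so the sizes of these differences are uncertain. Alas2 was lower in sh14 than in sh133 (-2.49 ± 0.21, adjusted p = 8.04e-05), by -2.67 and -2.31 at 6 and 12 h within run 1. Stat5a was higher in sh14 (0.55 ± 0.10, adjusted p = 0.00534). Of 52 G2-M and mitosis genes 20 were lower in sh14 (30 adjusted over the list alone), such as Kif2c (-0.92) and Ndc80 (-0.89), and of 49 S phase genes 8 were lower (10 adjusted over the list alone). Camera called both (adjusted p = 1.6e-10 and 3.3e-06, but adjusted p = 0.87 and 0.90 with an estimated correlation). Mast cell markers were higher in sh14 in 6 of 12 cases (7 adjusted over the list alone; adjusted p = 0.00022, and adjusted p = 0.29 with an estimated correlation), and erythroid terminal genes lower in 10 and higher in 3 of 28 (12 and 3 adjusted over the list alone; adjusted p = 0.00094, and adjusted p = 0.63 with an estimated correlation). Interferon response genes were higher in 9 and lower in 1 of 30 (11 and 1 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.87 with an estimated correlation), and cholesterol synthesis genes higher in 3 and lower in 2 of 20 (8 and 2 adjusted over the list alone; adjusted p = 0.012, adjusted p = 0.90 with an estimated correlation, and 0.92 without the run term). The mean of the cholesterol list was higher in sh14 at 6 h (7.34 against 6.96) and 12 h (7.30 against 7.09) but lower at 1 h (7.13 against 7.26) and 22 h (6.70 against 7.31). Camera called 6 lists, and 0 with an estimated correlation. In all 1856 genes passed, 955 higher and 901 lower in sh14, and 2366 passed within run 1 alone. Chromosomes 12, 6 and 4 held 13.9%, 13.1% and 11.4% of the genes higher in sh14, against 3.6%, 5% and 6.3% of the genes tested. Chromosome 13 held 9.4% of the lower and 7.6% of the higher genes, against 3.5% of the genes tested.

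From 1 h to 22 h most of the fixed red cell and heme genes rose, and most immediate early and ERK feedback genes fell. Slc25a37, the mitochondrial iron carrier, rose 6.17-fold (log2 2.62 ± 0.13 SE, limma adjusted p = 8.73e-06). Alas2 rose 4.03-fold (2.01 ± 0.18, adjusted p = 8.98e-05), by 1.32, 2.45 and 2.27 in scr, sh14 and sh133. Egr1, an immediate early transcription factor gene, fell 62.6-fold (-5.97 ± 0.31, adjusted p = 8.73e-06), and Vim, the intermediate filament vimentin, fell too (-5.66 ± 0.15, adjusted p = 3.1e-08; 1.39 in sh133 at 22 h, near background). Each of these moved the same way in all 3 lines.

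The other leading risers were Hbb-b2 (2.28; a globin probe set that may read several near-identical genes), Mcpt2 (2.17), Trim10 (2.12), the dematin gene Dmtn (2.12), Vsir (2.07), Epb42 (2.05), Hemgn (2.04), Cyp2c29 (2.02), the water channel gene Aqp1 (2.01) and Rhd (1.97), with adjusted p from 8.73e-06 to 0.00157. The leading fallers were Slc7a8 (-4.20), Hpgd (-4.09), Anxa2 (-3.78), Gask1b (-3.67), Etv5 (-3.55), Trnp1 (-3.49), the histidine decarboxylase gene Hdc (-3.29), the MAP kinase phosphatase gene Dusp4 (-3.25), Hhex (-2.54) and the glucocorticoid-induced kinase gene Sgk1 (-2.51), with adjusted p from 8.73e-06 to 0.00121. Vsir and Aqp1 at 1 h, and Hpgd, Gask1b, Etv5 and Dusp4 at 22 h, were near background in at least 1 line, so the sizes and order of these changes are uncertain. The erythroid master regulators Klf1 (1.25, adjusted p = 3.79e-05) and Gata1 (0.74, adjusted p = 0.000902) and the receptor gene Epor (0.60, adjusted p = 0.00503) rose. Kit, the stem cell factor receptor (-1.33, adjusted p = 0.00101), Myb (-0.79, 0.00328), Stat5a (-0.51, 0.00288), Plcg2 (-0.48, 0.00773) and Stat5b (-0.45, 0.0445) fell, and Jak2 (-0.28, 0.127) and Plcg1 (-0.14, 0.473) did not pass. In all 2291 genes passed, 1107 higher and 1184 lower, 2257 of them with the same sign in all 3 lines. The 1 h and 22 h arrays of a line were always in the same run, so these changes are within-run values. Across genes the 22 h minus 1 h changes correlated at 0.41 between scr and sh14, 0.67 between scr and sh133 and 0.62 between sh14 and sh133. With only the 1 h and 22 h arrays in the fit the count was 865, and it fell to 1146 without the sh133 array at either 1 or 22 h.

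**Figure D2:**
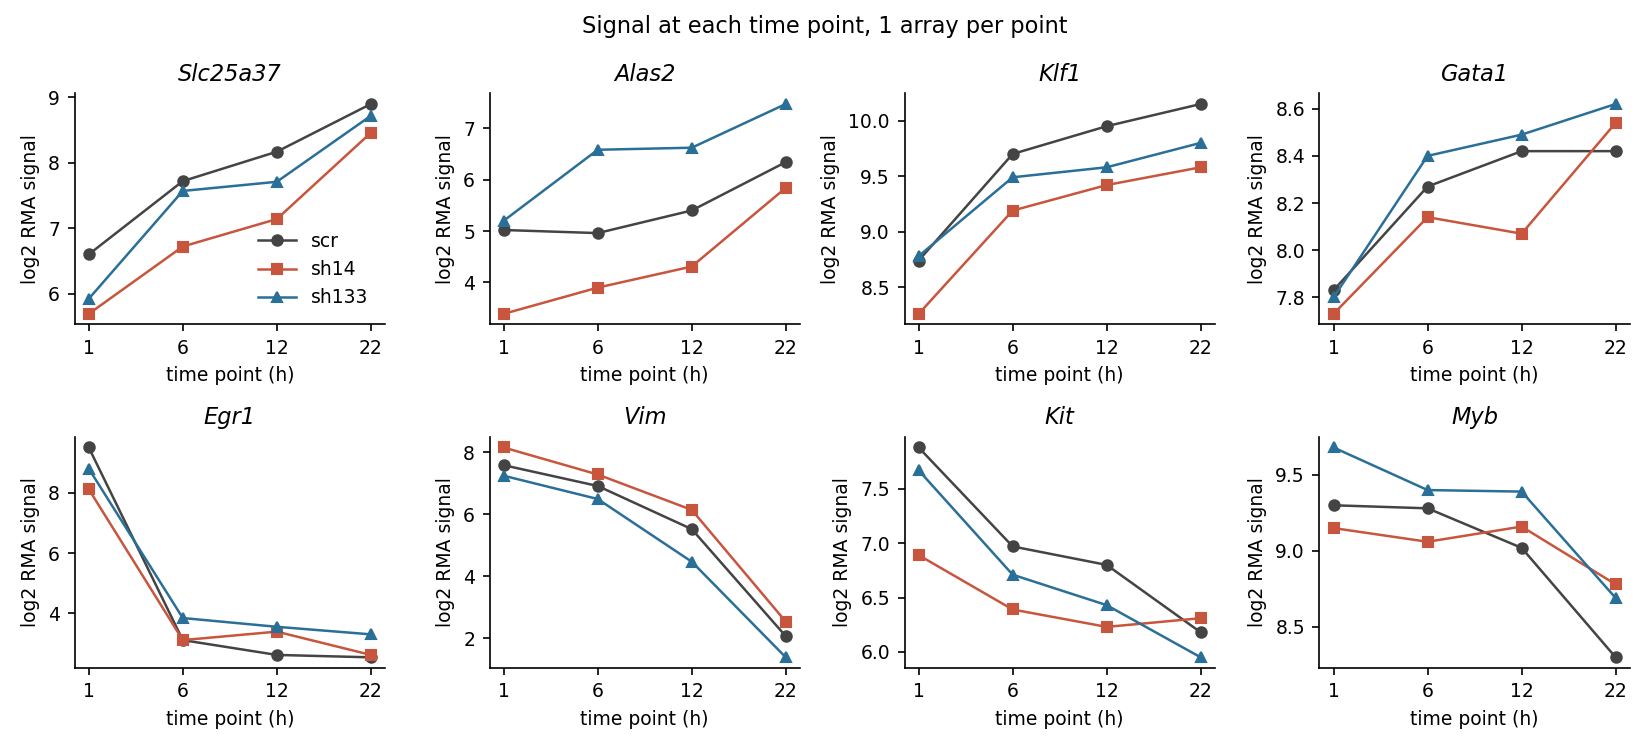
Log2 RMA signal (vertical axis, own scale per gene) of 4 genes that were higher at 22 h and 4 that were lower, at the 4 time points in hours (evenly spaced on the horizontal axis), 1 array per point. Egr1 drops from between 8.11 and 9.49 at 1 h to between 3.12 and 3.85 at 6 h, while Vim declines over the whole course in all 3 lines.

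Of 28 erythroid terminal genes 21 rose and 0 fell (21 and 1 adjusted over the list alone), and camera called the list at an adjusted p of 4.3e-14, held with an estimated correlation (adjusted p = 0.047). Heme synthesis and iron uptake rose in 16 of 21 genes (18 adjusted over the list alone), with Alad (1.86) and Uros (1.68) next to Alas2 (adjusted p = 1.2e-12, and adjusted p = 0.026 with an estimated correlation). Erythroid transcription factors rose in 12 of 19 (also 12 adjusted over the list alone), led by Sox6 (1.89), Klf1, Klf3 (1.04) and Bcl11a (1.00) (adjusted p = 4.4e-07, and adjusted p = 0.047 with an estimated correlation). Immediate early and ERK feedback genes fell in 18 of 30 and rose in 4 (19 and 4 adjusted over the list alone), with Egr1, Etv5, Dusp4 and Klf6 (-2.24) falling most (adjusted p = 1.1e-08, and adjusted p = 0.047 with an estimated correlation).

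The remaining 11 called lists lost their call with an estimated correlation, and 10 of them are described here. Glucocorticoid targets fell in 11 of 21 genes and rose in 1 (14 and 1 adjusted over the list alone), with Sgk1, Zbtb16 (-1.57), Pik3ip1 (-1.56) and Klf9 (-1.41), and adjusted p = 0.13 with an estimated correlation. EpoR-JAK2 signalling members fell in 10 of 26 and rose in 2 (12 and 2 adjusted over the list alone), with the feedback inhibitor gene Cish (-1.35) and Sh2b3 (-1.03), and adjusted p = 0.34 with an estimated correlation. EpoR-STAT5 targets fell in 10 of 25 and rose in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation), and progenitor and SCF-Kit genes fell in 10 of 23 (12, with 1 higher, adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), with Ets1 at -2.35 and Angpt1 (near background at 22 h) at -2.04. ATF4 and unfolded protein response genes fell in 10 of 38 and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation), with Chac1 (-1.84) and Atf3 (-1.48). G2-M and mitosis genes rose in 18 of 52 (30 adjusted over the list alone; adjusted p = 0.51 with an estimated correlation), led by Cdc25b (1.34), and S phase genes in 5 of 49 (4 adjusted over the list alone; adjusted p = 0.73 with an estimated correlation), led by Cdc6 (1.19). Ribosome biogenesis genes fell in 9 of 44 (also 9 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation), cytosolic ribosomal proteins in 3 of 27 (1 adjusted over the list alone; adjusted p = 0.69 with an estimated correlation) and housekeeping genes in 4 of 11 (also 4 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), among them Gusb (-0.70) and Pgk1 (-0.47).

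**Figure D3:**
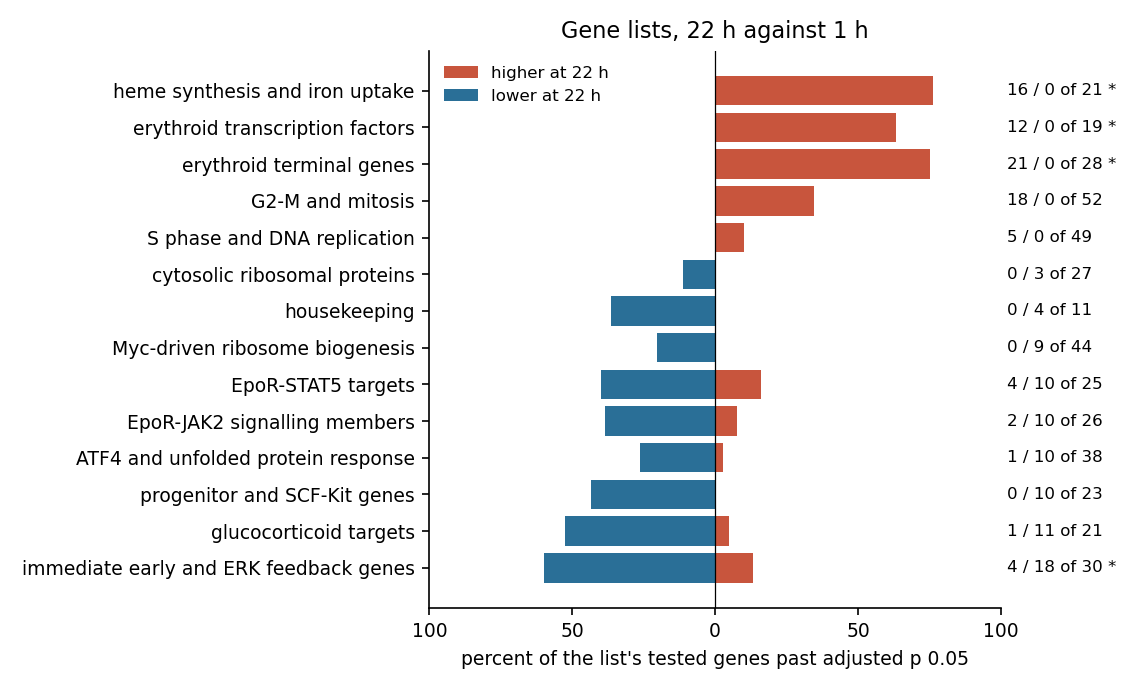
Percent of each list's tested genes past an adjusted p of 0.05 at 22 h against 1 h, higher to the right and lower to the left, for 14 of the 15 lists called by camera; the numbers beside each bar give higher, lower and tested genes. An asterisk marks the 4 lists whose call held with an estimated correlation, the erythroid terminal, heme, erythroid transcription factor and immediate early lists.

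The other lists were not called at 22 h against 1 h. Mast cell and basophil markers had 2 higher and 6 lower of 12 (3 and 6 adjusted over the list alone; list adjusted p = 0.086), with Hdc, Ms4a2 (-1.30) and Cpa3 (-1.06) lower, the last 2 near background at 22 h. Glycolysis and hypoxia had 2 higher and 8 lower of 31 (4 and 10 adjusted over the list alone; 0.12). Cell cycle inhibitors and D cyclins had 8 higher and 4 lower of 23 (also 8 and 4 adjusted over the list alone; 0.36), with Gadd45a (1.39) and Btg2 (1.32) higher and Cdkn1a (-1.40) lower. p53 targets had 6 higher and 3 lower of 21 (8 and 3 adjusted over the list alone; 0.31). Autophagy and lysosome had 9 higher and 3 lower of 34 (10 and 4 adjusted over the list alone; 0.17). The PLC and PKC pathway had 3 higher and 6 lower of 32 (the same counts adjusted over the list alone; 0.36), with Tec (-1.86) and Lat (-1.48) lower. Apoptosis regulators had 1 higher, Bcl2l11 (1.13), and 3 lower, such as Mcl1 (-1.02), of 25 (the same counts adjusted over the list alone; 0.63).

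For the interferon response the counts were 3 and 6 of 30 (list adjusted p = 0.85), for megakaryocyte markers 4 and 1 of 19 (0.38), for variant histones 2 and 3 of 25 (0.89) and for replication-dependent histones 0 and 3 of 7 (0.24). They were 0 and 1 of 13 for calcium-NFAT targets (0.66), 1 and 1 of 48 for oxidative phosphorylation (0.68), 0 and 2 of 16 for heat shock (0.89) and 0 and 0 of 20 for cholesterol synthesis (0.68). Markers of other cell types gave 1 and 2 of 15 for myeloid (0.74), 0 and 0 of 10 for lymphoid (0.52) and 1 and 1 of 11 for fibroblast and stromal cells (0.89). Adjusted over the list alone, these counts differed for 4 lists: megakaryocyte markers (5 and 1), oxidative phosphorylation (0 and 0), heat shock (0 and 0) and myeloid markers (2 and 2). Median and mean had opposite signs for the interferon list (0.04 and -0.02) and the stromal list (0.02 and -0.40).

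Egr1, Etv5 and Klf1 had moved most of their 22 h distance by 6 h, whereas Vim and Alas2 had not. At 6 h, limma called 616 genes against 1 h (371 higher, 245 lower), and at 12 h 895 (547 higher, 348 lower). Egr1 had fallen by 5.53 at 6 h (adjusted p = 0.000225) and Etv5 by 2.78 (adjusted p = 0.000907). Vim had fallen by 0.69 at 6 h (adjusted p = 0.043) and by 2.21 at 12 h (adjusted p = 0.000273). Slc25a37 had risen by 1.17 at 6 h (adjusted p = 0.00323) and by 1.50 at 12 h (adjusted p = 0.00081), and Klf1 by 0.92 and 1.10. Alas2 differed by 0.36 at 6 h (adjusted p = 0.398) and 0.65 at 12 h (adjusted p = 0.0914) without passing. Of the genes called at 6 h, 256 higher and 203 lower were also called in that direction at 22 h (32.4 and 22.9 for independent lists), and 5 went the other way. At 12 h, 396 higher and 310 lower were shared with 22 h (47.8 and 32.5 for independent lists). These comparisons share the 1 h arrays, which adds to the overlap. Without the scr array at 6 h the 6 h count was 97, and without the scr array at 12 h the 12 h count was 221.

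Whether knockdown altered the time course was tested as a difference of slopes. Only 4 genes passed in limma, against 2049 at an unadjusted p under 0.05. The linker histone gene H1f2 had 22 h minus 1 h differences of -2.85 in scr, -0.71 in sh14 and -0.80 in sh133 (slope difference 0.46 ± 0.04 per doubling of hours, adjusted p = 0.0108). Ypel3 (0.44) and Tent5c (0.37) also had higher slopes with knockdown and Syne3 a lower slope (-0.34), each at an adjusted p of 0.0495. Patl2 (0.33, adjusted p = 0.0748) and Btn1a1 (0.43), Trmt61a (-0.28), Dusp12 (-0.24), Thg1l (-0.21) and Enoph1 (-0.23), each at 0.0819, did not pass. At adjusted p from 0.235 to 0.961, none of Plcg1 (0.08), Epor (0.03), Jak2 (0.10), Gata1 (0.02), Klf1 (-0.05), Kit (0.10), Myb (0.07), Plcg2 (-0.01), Stat5a (0.02) or Stat5b (0.13) passed. Of 49 S phase genes 0 passed (35 lower adjusted over the list alone), and camera called the list lower at an adjusted p of 2.4e-22, and adjusted p = 0.32 with an estimated correlation. Ribosome biogenesis was called lower too (0 of 44 passing, 4 lower adjusted over the list alone; adjusted p = 5.5e-09, and adjusted p = 0.32 with an estimated correlation). Megakaryocyte markers were called higher (0 of 19 passing, 7 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.32 with an estimated correlation). The remaining 9 called lists (G2-M and mitosis and cholesterol synthesis lower, the others higher) had adjusted p from 0.32 to 0.63 with an estimated correlation. The count of 4 genes was 0 without the scr array at 1, 6 or 12 h, and 361 without the sh133 array at 1 or 22 h.

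**Figure D4:**
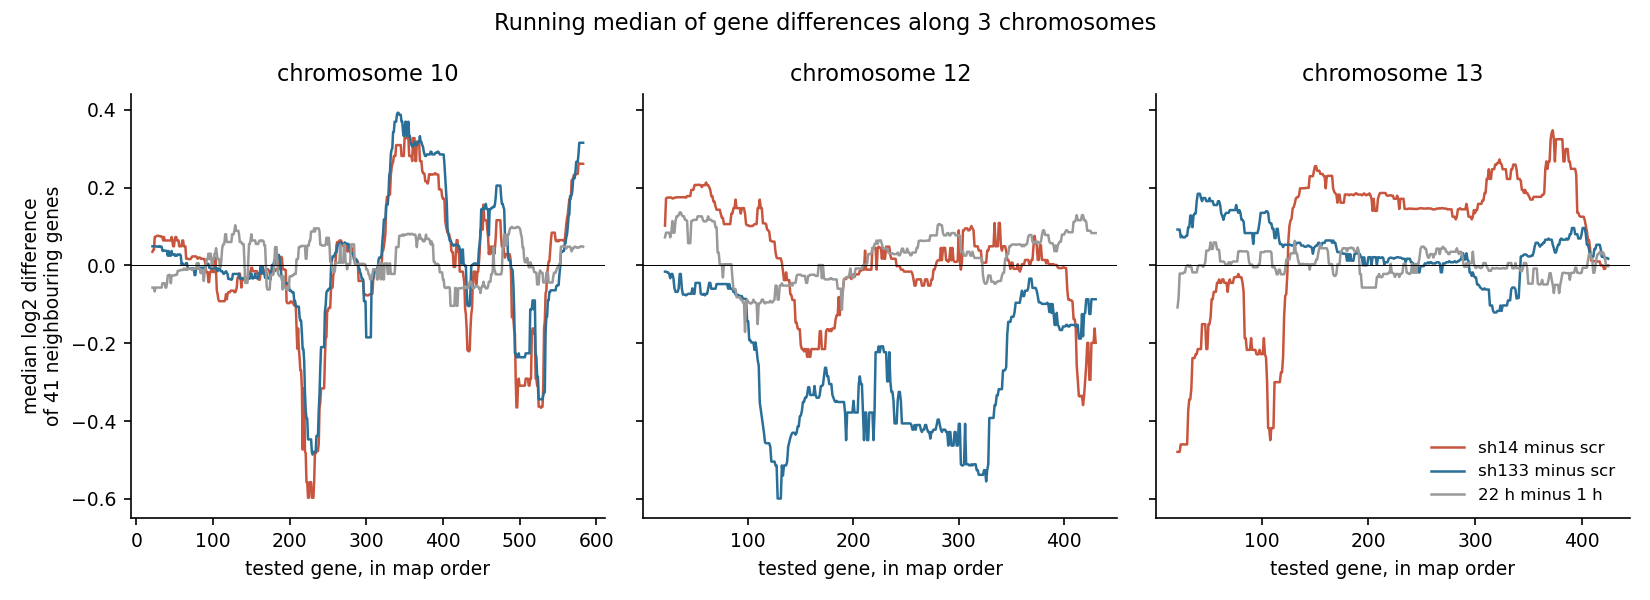
Median log2 difference of 41 consecutive tested genes (vertical axis) in map order (horizontal axis, gene number) on chromosomes 10, 12 and 13, for sh14 minus scr, sh133 minus scr and 22 h minus 1 h. The lowest medians are -0.60 for sh14 on chromosome 10, -0.60 for sh133 on chromosome 12 and -0.48 for sh14 on chromosome 13, while both hairpins follow each other on chromosome 10.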

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

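Of the tests in this part, those on knockdown depth, neighbouring pairs, stretches, the chromosome 12 stretch, signal compression and array labels were chosen only after the result was seen. The others were planned.

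The hairpin lines, which target the same gene, differed from each other in 1856 genes, by a test of the difference itself. Those named by the rule, with sizes from the fit with the run term and several near background on the lower side, were Csn1s2a (4.19), Sphkap (4.06), Csn1s2b (3.30), Fcer1a (3.12), Sapcd1 (2.75), Cxcl3 (-4.45), Cdh2 (-3.21), Gstt1 (-3.06), Ly6k (-2.97) and Fkbp9 (-2.95), of which Csn1s2a (2.92), Csn1s2b (2.25) and Cxcl3 (-2.97) moved most without that term. A difference of array run is argued against as the whole cause, since the run 1 arrays alone called 2366 genes, while a different depth of knockdown stays open: 37.1% of these genes had the same sign against scr in both lines, but they were chosen for a difference between the lines, which itself parts the signs. A different stage of maturation is argued against as the whole cause by an r of -0.19 between the hairpin difference and the change over time (-0.27 among the called genes), but the erythroid terminal and G2-M lists differ in sh14 in the direction opposite to their change with time, so a part in it stays open. In sh14 minus sh133, medians of 41 neighbouring genes went beyond all 1000 shuffles on chromosomes 13 (-0.66), 12 (0.64), 6 (0.48) and 4 (0.28). A local difference in copy number or expression between the lines may thus account for part of these calls, and its origin was not tested. Off-target effects of a hairpin and other differences between the cell lines that arose in culture or infection stay open and untested, since each hairpin is represented by 1 line.

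Genes that are neighbours on a chromosome moved together between the lines. Neighbouring pairs called in the same direction numbered 79 in sh133 against scr (at most 33 in shuffles) and 26 in sh14 (at most 15), but 22 h against 1 h also exceeded its shuffles (316 against 245), and stretches beyond all 1000 shuffles lay on 5 chromosomes in sh14, 2 in sh133 and 0 for 22 h minus 1 h, so a local difference in copy number or expression between the lines may account for part of the calls. The planned test for whole chromosomes left that question open, with chromosome 12 of sh133 at -0.17 at the time nearest 0. The chromosome 12 stretch of sh133 was at -0.40 within run 2, which argues against the array run, and at -0.01 in sh14, which argues against a response to the knockdown common to both hairpins. On chromosome 10 both hairpins were lower over the same genes (-0.60 in sh14 and -0.45 in sh133). Over another stretch of that chromosome both were higher than scr (0.31 in sh14 and 0.39 in sh133). A difference of the scr line and a response to knockdown stay open there.

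Plcg1 was at 85.0% of scr with the hairpins, a small difference for the targeted gene. A general compression at this signal is argued against for modest differences. In sh133 minus scr, genes of the chromosome 12 stretch near the signal of Plcg1 had a median of -0.47 and bright ones -0.45 (104.3%). These are other probe sets, so compression particular to the Plcg1 probe set, or of a larger difference, was not tested. An array carrying another line's label is argued against too, since 8 of 8 sets of arrays had the lowest array where its label put it, although that leaves the naming of whole lines untested. A weak knockdown at these times, a probe set that reads another transcript form, and a loss of the hairpin in culture stay open and untested.

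The actin 3' minus 5' difference of scr at 22 h (0.63) stood far from the other scr arrays (0.55 to 0.56), and that of sh133 at 22 h (0.34) from the other sh133 arrays (0.51 to 0.53). Plcg2 in scr at 1 h (4.98) stood above the other scr arrays (4.58 to 4.64), and Stat5a in sh14 at 22 h (5.20) below the other sh14 arrays (5.60 to 5.68). These were 4 of 84 sets tested, and chance gives about 1 in 20. A test of slopes found 4 genes whose time course differed with knockdown: H1f2 (0.46), Ypel3 (0.44), Tent5c (0.37) and Syne3 (-0.34). Of the 9211 probe sets with no gene name, which no comparison of genes used, 3854 were tested by themselves. Among these, 7 were called with knockdown (3 higher, 4 lower) and 448 at 22 h (171 higher, 277 lower).

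Splits of the same arrays, 100 for each comparison with the real one counted among them, were tested for results as large. Few splits were as large for knockdown (276 genes, highest other split 2307, 2 of 100 as large) and for sh133 (622, highest other 1488, 4 as large). The same held for sh14 against sh133 (1856, highest other 1010, 1 as large, the real split). With 1 line per shRNA, splits that mix arrays of different lines cannot exclude a chance difference between lines, so no exclusion is drawn for these comparisons. For 22 h (2291, highest other 558, 1 as large) and for 12 h (895, highest other 205, 1 as large) only the real split was as large. This argues against a random order of the arrays in time within each line. The other splits carry the time differences in their spread, which lowers their counts. An effect of culture or handling common to the arrays of a time point cannot be excluded in this way. For knockdown by time 2 of 100 splits called as many genes (4, highest other 4), and a count this small that another split equals does not carry an exclusion of chance. Nor can chance be excluded by such splits for sh14 against scr (388, highest other 1010, 6 as large) or for 6 h (616, highest other 1080, 5 as large). The other large splits for sh14 kept all arrays of a line together. Those for 6 h set mostly 1 h arrays against mostly 22 h arrays. They thus hold differences between lines or times and do not measure chance alone. The split with 2307 genes relabels whole lines, several times the real count, which points to a structure of the samples by line. The splits between shRNAs thus show that the lines differ, not that the difference comes from the knockdown. For gene lists at the preset correlation, knockdown exceeded the other splits by a margin of 1 list (12 lists, highest other 11, median 5, 1 as large), with the same limit of 1 line per shRNA. With an estimated correlation 0 lists were called. Chance cannot be excluded for the lists at 22 h (15 lists, highest other 18, 7 as large).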

How the results depend on the processing

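Leaving out the genes of chromosome 12, or of chromosomes 10 and 12, was chosen after the result was seen; the other alternatives were planned. The combined knockdown difference of Plcg1, read from its brightest probe set, stayed below 0 and missed the threshold in the alternatives run, at -0.41 to -0.13 with each array left out. It was -0.05 with the mean over its probe sets, which takes in those near background (-0.15 and 0.22). For sh14 alone the Plcg1 difference passed with no run term (-0.38, adjusted p = 0.0201). The knockdown count of 276 was 2049 with no run term (260 of the 276 shared in direction), 452 with array weights, 143 with no time term and so no block for the matched times, and 150 without chromosomes 10 and 12. The 622 genes of sh133 became 1592 with no run term, 254 in run 2, 370 with only sh133 and scr arrays, and 305 without chromosomes 10 and 12. The 388 of sh14 became 3003, 858 with weights and 590 with a line in log2 hours, and the 1856 between hairpins 3132 and, with weights, 3468. Testing every probe set gave 4034, 1003 and 1487 for 22, 6 and 12 h, with more features tested. The 22 h count was 865 on the 1 and 22 h arrays alone, and the 6 h count 946 with no run term. For knockdown by time, the 60th percentile filter, every probe set, quantile normalization, centred arrays and the line each gave 1 gene, the mean over probe sets and the 1 and 22 h arrays alone 0 in limma (1935 and 1087 at an unadjusted p under 0.05), the trend and robust prior 112 and weights 489. With an estimated correlation 0 lists were called for knockdown, for each hairpin and for knockdown by time, and 4 for 22 h. For sh133, 9 lists were called with no run term and 7 with no filter, and the hairpin correlation was 0.40 with no run term. Reversed were Rbl1 at 22 h with the mean over probe sets (-0.03, adjusted p = 0.904), Fcer1a with knockdown in run 2 (-0.06, adjusted p = 0.935, no sh14 array) and the cholesterol synthesis list in sh14, called higher with the run term and lower without it (adjusted p = 0.017, median -0.18). Over the named genes, 7021 called values stayed called in direction, 1233 lost the call and 2 reversed. With arrays left out singly, knockdown gave 59 to 384 genes: 118 and 97 without sh14 at 6 and 12 h, 59, 77, 86 and 94 without sh133 at 1, 6, 12 and 22 h, and 156 and 139 without scr at 6 and 12 h. sh133 gave 135 to 734 (244 and 135 without sh133 at 1 and 22 h, 407 and 399 without scr at 6 and 12 h). sh14 gave 87 to 555 (129 without sh14 at 6 or 12 h, 119, 96 and 87 without sh133 at 1, 6 and 12 h, 240 without scr at 6 h). The hairpin difference gave 390 to 2206 (1072 and 900 without sh14 at 6 and 12 h, 413 and 390 without sh133 at 6 and 12 h), and 22 h gave 1146 to 2273 (1146 without sh133 at 1 or 22 h). At 6 h the range was 97 to 730 (188 and 392 without sh14 at 6 and 12 h, 236 without sh133 at 6 or 12 h, 311, 97 and 376 without scr at 1, 6 and 12 h), and at 12 h 221 to 1110 (273 without sh14 at 12 h, 519 without sh133 at 6 or 12 h, 491 and 221 without scr at 1 and 12 h). Knockdown by time gave 0 to 361 in limma: 0 without scr at 1, 6 or 12 h (935, 1838 and 1790 at an unadjusted p under 0.05), 2 without scr at 22 h or sh14 at 6 h, 1 without sh14 at 1 or 12 h or sh133 at 6 or 12 h, 11 without sh14 at 22 h, and 361 without sh133 at 1 or 22 h. Unless the alternative itself tests fewer or more features or arrays, the cause was not tested. At dim signal the arrays limit what can be seen, and Plcg1 lies at the 46.5th percentile.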

Other observations

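Single genes of sterol synthesis and of megakaryocytes also differed between the hairpin lines, in lists that went both ways (the cholesterol synthesis list had adjusted p = 0.90 with an estimated correlation). Insig1, which encodes a sterol-regulated membrane protein that holds back sterol synthesis, was lower in sh14 than in sh133 (-2.31 ± 0.24 SE, adjusted p = 0.00029, and -1.99 and -2.31 at 6 and 12 h within run 1), while the sterol reductase genes Tm7sf2 (1.59 ± 0.12, adjusted p = 3.6e-05) and Dhcr7 (1.00 ± 0.16, adjusted p = 0.00273) were higher. Against scr, Insig1 differed by -2.17 in sh14 (adjusted p = 0.0129) and by 0.14 in sh133 (adjusted p = 0.84). Of 19 megakaryocyte markers 2 were higher and 5 lower in sh14 than in sh133, also adjusted over the list alone, and the list was not called (adjusted p = 0.62). Cd9 (1.66) and Itga2b (1.46) were higher and Pf4 (-2.34, adjusted p = 0.0117) and Plek (-1.43) lower.

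From 1 h to 22 h several stress and metabolic genes moved in lists that were not called as a whole. Of those named here, Ddit4, Btg2 and Foxo3 also belong to lists that were called. The hypoxia and glycolysis genes Egln3 (-0.90), Pkm (-0.87) and Hk2 (-0.79) fell, and Ddit4 fell by 0.93 (adjusted p = 0.016). I/11 cells lack p53, and among genes known as its targets Perp (-1.25) and Cdkn1a (-1.40) fell while Gadd45a (1.39) and Btg2 (1.32) rose. The lysosomal proteases Ctsb (0.64) and Ctsd (0.49, named after its value was seen) and the autophagy regulator Foxo3 (0.66) rose, and Rb1 rose by 0.89 (adjusted p = 0.0002).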
